A study of Mus musculus with 9 samples.

How the data were processed

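Polyadenylated RNA of CD8 T cells from wild-type mouse spleen was measured in 9 libraries, 3 each of control, D-2HG and L-2HG. Cells were lysed, RNA was captured on beads, cDNA was primed with oligo(dT) and amplified by a limited PCR, and libraries were made by transposase tagmentation, per the labels' protocols. The deposited counts are whole numbers per gene symbol and library, made with STAR 2.7.3a and featureCounts on genome build mm10, per the submitters' processing notes, which give no settings and no annotation release. The deposited signal values of a further table are these counts divided by 1 size factor per library, from DESeq2 according to the table's title, and recomputed counts lay within 6.56e-05 of whole numbers. Those values served to look up gene identifiers and to compare scalings and entered no test. Positions, exon lengths and GC content came from GENCODE M21, and 215 of 55011 symbols had no position there. Raw reads were not analysed here.

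Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Of 55011 genes, 11256 had no count in any library, and 10235 passed filterByExpr with the group factor (minimum count of 10). Libraries were scaled by TMM and given as CPM, the counts over the scaled totals. A single model with 1 mean per group and 6 residual degrees of freedom was fitted to all 9 libraries by edgeR's robust quasi-likelihood method, and D-2HG against control, L-2HG against control and D-2HG against L-2HG were tested by its F test with Benjamini-Hochberg adjustment over all tested genes in each comparison. A gene passed at adjusted p under 0.0500. Intervals of single genes are 95% intervals of the log2 fold change from the same fit and are not adjusted for the number of genes. The biological coefficient of variation was 0.210. Replicates of a group differed by more than counting error, with chi-square per degree of freedom from 6.07 to 42.3 over pairs of replicates.

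Gene lists for 21 pathways and 11 cell types and RNA quality, the comparisons, the tests and most alternatives were written before the data were examined. Lists were tested with camera on log2 CPM (prior count 2, preset correlation between genes 0.01), adjusted over the pathway lists of a comparison, and over the cell type and RNA quality lists as a family of their own. Members past the threshold were counted over all genes and also adjusted over the list alone. Each list was also tested with a correlation estimated from the data, with fry and with camera on ranks. Ranges over camera settings leave out fry, which is given apart where it changes a call. List scores are means of log2 CPM over tested members. They were compared with intervals from limma's moderated variance, in which the variance of each list is drawn towards a value common to all lists. Shares of counts in Gm10800 and Gm10801, in transcripts encoded by mitochondria and in sensory receptor genes were compared between groups by exact permutation. Of 1781 sensory receptor genes 1692 were used, without the 5% that had the most reads per base of exon. Control replicate 2 was set against control replicates 1 and 3, which received the same treatment, as a comparison without a compound. Changes with a compound given beside it are against all 3 controls, replicate 2 included, so that the values do not share a baseline. A shift of replicate 2 in the direction of a compound makes the change with that compound smaller.

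Genes were named by a rule fixed before the data were examined. For each comparison it takes the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among those past the threshold with a mean of at least 5 CPM and CPM ranges that do not overlap between the groups. Chance gives such ranges to 10% of unchanged genes with 3 against 3, and predicted genes and pseudogenes were left out. It adds fixed genes (Ifng, Il2, Tnf, Gzmb, Myc, Cd69, Il2ra, Ldha, Hk2, D2hgdh and Idh1), the 3 members with the smallest adjusted p of each list past the threshold and at most 1 of each other list. Some genes that the rule takes are not reported here. Other members of the fixed lists are named where they explain a count. Cd8a, Ighm, Ddx58, Ifit2, Gm1966, Gm10800, Gm10801 and the genes of the lists drawn up later were chosen after their values were seen.

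Alternatives fixed in advance were DESeq2's Wald test over all genes it keeps, limma-voom with sample quality weights, DESeq2 size factors, library totals without TMM, no count filter, a mean count of at least 50, a fit of only the groups compared, the replicate number as a block, thinning to the smallest library, a minimum change of 2-fold and leaving out each library in turn. Chosen after seeing the data were a genomic DNA background (reads per base of exon in 1692 sensory receptor genes times the exon length of each gene) subtracted from the counts and a restriction to genes whose predicted background was under 10% of the counts. So were the log2 satellite share as a covariate, leaving out D-2HG replicate 3 and L-2HG replicate 2, the deposited size factors, offsets for exon length and GC content, and a fit of the 5 libraries of like satellite share (control replicate 2, D-2HG replicates 1 and 2, L-2HG replicates 1 and 3). In the last, the lone control is assumed to vary like the other groups. Unchanged groups were simulated 40 times against the fitted control values to show what shared controls give.

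The procedure was tested on simulated data of the same depth and spread, with 200 changed genes among 10235 in each comparison. Genes changed 2-fold were called in 60%, 36% and 35% of cases and genes changed 4-fold in 93%, 90% and 80%, in the order D-2HG against control, L-2HG against control and D-2HG against L-2HG. False calls numbered 20, 9 and 8 of 173, 135 and 123 calls. A shifted list was called in each comparison and none of the 20 other lists was. Genes were drawn independently, so these data do not test how list calls behave when genes are correlated.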

Results

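RNA was sequenced from CD8 T cells of mouse spleen, the lymphocytes that kill infected and tumour cells. Naive cells were stimulated for 6 h on plates coated with 4 µg/mL of antibodies to CD3, part of the T cell receptor complex, and to the costimulatory receptor CD28. Cells were left untreated (control) or received 20 mM D-2HG or 20 mM L-2HG from the start of the stimulation, with 3 libraries per group and 9 in all. D-2HG and L-2HG are the mirror-image forms of 2-hydroxyglutarate and differ in the configuration at the carbon that carries the hydroxyl group. D-2HG is the form that mutant isocitrate dehydrogenases produce in some tumours, and the study concerned what it does to the metabolism and function of these cells. Gene counts totalled 4773400, 1990896 and 5731885 in control replicates 1, 2 and 3. They totalled 2811625, 4139601 and 2431371 with D-2HG, and 2562692, 562627 and 2060411 with L-2HG, so that L-2HG replicate 2 had the lowest depth. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

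The libraries also differed in measures that the groups do not define. Gm10800 and Gm10801, predicted genes that match satellite repeats, took 1.43% (1.42 to 1.44), 5.35% (5.32 to 5.38) and 0.910% (0.902 to 0.917) of the counts in control replicates 1, 2 and 3 (exact Clopper-Pearson 95% intervals, counting error only). Both genes were kept among the genes tested and in the totals behind CPM. The share was 6.83% (6.80 to 6.86), 3.79% (3.77 to 3.81) and 17.0% (17.0 to 17.1) with D-2HG, and 6.71% (6.68 to 6.74), 24.4% (24.3 to 24.6) and 7.98% (7.94 to 8.02) with L-2HG. The group means were 2.56 ± 2.43% in control, 9.22 ± 6.95% with D-2HG and 13.0 ± 9.90% with L-2HG (SD, n = 3; two-sided exact permutation p = 0.2 and 0.1 against control, where 3 against 3 libraries cannot go below 0.1). Transcripts encoded by mitochondria took 2.66 ± 0.416%, 1.54 ± 0.481% and 1.49 ± 0.322% of counts (exact permutation p = 0.1 for each compound). Olfactory, vomeronasal and trace amine-associated receptor genes, silent in T cells, were counted over 1692 genes. These genes held 459 ± 324, 988 ± 210.1 and 1949 ± 1128 CPM of the unscaled totals (exact permutation p = 0.2 and 0.1).

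**Figure D1:**
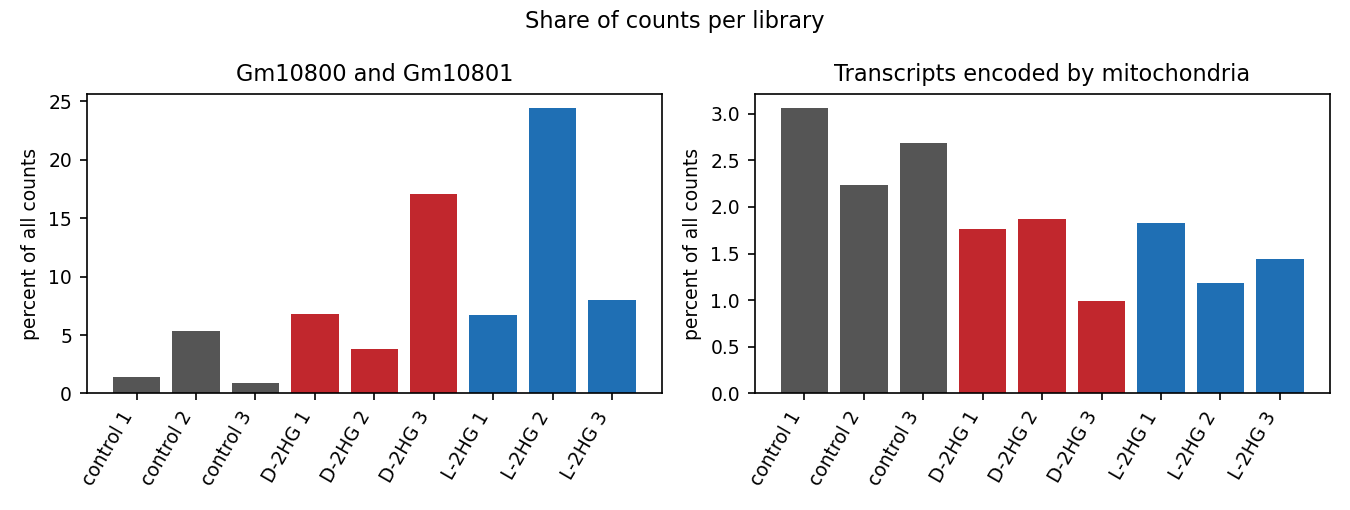
Share of all gene counts, in percent, held by the satellite-matching genes Gm10800 and Gm10801 (left) and by transcripts encoded by mitochondria (right), with 1 bar per library in grey for control, red for D-2HG and blue for L-2HG. Control replicate 2 stood nearer to the treated libraries than the other controls in the satellite share (5.35%), and each treated library had a lower mitochondrial share than each control.

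Markers of CD8 T cells were present in each group, at 918 ± 205, 784 ± 59.4 and 729.5 ± 111 CPM of Cd8a in control, D-2HG and L-2HG (SD, n = 3). Of the 9 tested members of the CD8 T cell list, Cd8b1, Cd3e, Cd3g and Trac fell and Themis rose with D-2HG, and Trac fell with L-2HG (camera adjusted p = 0.0712 and 0.332). Of the B cell markers, Ighm, the heavy chain of immunoglobulin M, fell from 239 ± 73.3 CPM to 127 ± 0.223 and 151 ± 33.2 (edgeR adjusted p = 0.0114 and 0.0490; list camera adjusted p = 0.135 and 0.419). Of 3 tested dendritic cell markers, Zbtb46 rose with L-2HG by 1.10 on the log2 scale (edgeR adjusted p = 0.0382; list camera adjusted p = 0.135 and 0.343). Camera gave adjusted p = 0.875 and 0.905 for CD4 T cell markers, 0.361 and 0.905 for the macrophage and monocyte list. It gave 0.875 and 0.792 for the NK cell list, and each of these lists but the first had a single tested member. The plasma cell, neutrophil, erythroid and platelet lists had no member above the count filter. In the list of RNA quality transcripts, mt-Nd1, mt-Nd2, mt-Nd4, mt-Cytb and mt-Atp6 fell with both compounds, while the nuclear RNAs Neat1 and Kcnq1ot1 rose (camera adjusted p = 0.0162 for each compound, adjusted p = 0.423 and 0.652 with an estimated correlation).

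The first comparison set cells stimulated with D-2HG against stimulated control cells. Genes induced by interferons were lower with D-2HG: 16 of the 25 measured members of the interferon-stimulated list fell (17 adjusted over the list alone) and no member rose. The mean log2 CPM of the list was 4.66 ± 0.04 in control and 3.12 ± 0.09 with D-2HG (SD, n = 3; camera adjusted p = 2.52e-12, adjusted p = 0.00356 with an estimated correlation, 7.07e-20 to 0.00356 over all camera settings). Gbp2, an interferon-inducible guanylate-binding protein (identifier ENSMUSG00000028270, chromosome 3, 142620602 to 142638008, mm10), fell from 282 ± 37.7 to 15.4 ± 1.86 CPM, a log2 fold change of -4.21 ± 0.24 (SE; edgeR adjusted p = 1.05e-09). Ly6a (identifier ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), the interferon-inducible surface antigen Sca-1, fell from 106 ± 27.9 to 4.40 ± 2.16 CPM (edgeR adjusted p = 6.60e-08). The immunity-related GTPases Igtp and Iigp1 fell to 31.4 ± 1.55 and 4.82 ± 1.56 CPM from 247 ± 75.6 and 42.4 ± 10.8 (edgeR adjusted p = 7.94e-07 and 4.46e-06). Gbp7, the nucleic acid sensor Zbp1 and the chemokine Cxcl10 fell, with log2 fold changes of -2.53, -2.99 and -3.29 (edgeR adjusted p = 1.38e-06, 0.000100 and 0.00157). Members that did not pass included, chosen after their values were seen, Ifit2 at 0.78 (-0.67 to 2.23, 95% interval) and Ddx58 at 0.42 (-0.25 to 1.09). Gbp and Tgtp genes have near-identical copies and Igtp overlaps Irgm2, so that the split of reads among these is uncertain. Control replicate 2, the control with the highest satellite share, differed from replicates 1 and 3 by a median of 0.01 over the list on the log2 scale, against -1.89 for D-2HG.

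**Figure D2:**
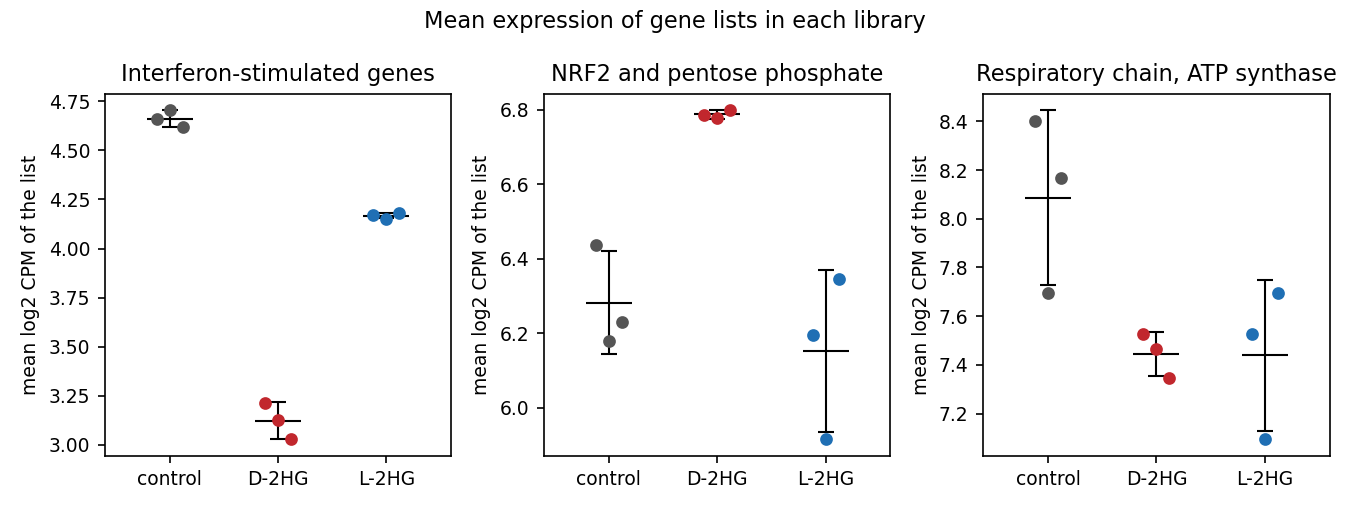
Mean log2 CPM over the tested members of 3 gene lists in each library (points), with the group mean (long bar) and SD (short bars, n = 3); the vertical axes do not start at 0. The interferon-stimulated list stood at 4.66 ± 0.04 in control, 3.12 ± 0.09 with D-2HG and 4.17 ± 0.01 with L-2HG, while the respiratory chain list spread over the controls from 7.69 to 8.40.

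Cytokine and cytotoxicity genes were also lower with D-2HG. Of 16 measured members, 6 fell (9 adjusted over the list alone): Ifng, Lta, Xcl1, Ccl3, Ccl4 and Fasl (camera adjusted p = 0.000133, adjusted p = 0.319 with an estimated correlation, 4.18e-05 to 0.319 over all camera settings). Ifng, which encodes interferon gamma (identifier ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), fell from 8.21 ± 3.15 to 0.914 ± 0.462 CPM (edgeR adjusted p = 0.00384). The chemokine gene Ccl3 fell from 714 ± 247 to 337 ± 30.8 CPM (edgeR adjusted p = 0.00627). Lta, encoding lymphotoxin alpha, fell from 381 ± 121 to 176 ± 23.4 CPM (edgeR adjusted p = 0.00627). The log2 difference was -0.24 for Tnf (95% interval -0.65 to 0.17), -0.56 for Il2 (-1.11 to -0.01) and -0.46 for the protease gene Gzmb (-1.24 to 0.32), none past the threshold (edgeR adjusted p = 0.372, 0.121 and 0.376). Among inhibitory receptor and exhaustion-associated genes, 6 of 10 fell (7 adjusted over the list alone; camera adjusted p = 0.00669, adjusted p = 0.319 with an estimated correlation, 0.000263 to 0.319 over all camera settings). Pdcd1, the gene of the receptor PD-1 (identifier ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), fell from 516 ± 136 to 222 ± 40.2 CPM (edgeR adjusted p = 0.00259). Cd200 fell from 49.7 ± 5.77 to 17.1 ± 3.44 CPM (edgeR adjusted p = 0.00199). Control replicate 2 differed from replicates 1 and 3 by a median of -0.34 over the cytokine list and 0.14 over the inhibitory list, against -0.55 and -0.96 with D-2HG.

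Nuclear genes of the respiratory chain and ATP synthase were lower with D-2HG, with 23 of 33 below control (30 adjusted over the list alone; camera adjusted p = 2.11e-09, adjusted p = 0.402 with an estimated correlation, 5.39e-11 to 0.402 over all camera settings). Cox5b, a subunit of cytochrome c oxidase, fell from 257 ± 62.9 to 129 ± 2.54 CPM (edgeR adjusted p = 0.00500). Ndufs8 of complex I fell from 222 ± 60.2 to 115 ± 9.48 CPM (edgeR adjusted p = 0.00858). Of 22 TCA cycle genes, 6 fell (7 adjusted over the list alone) and Ogdh rose (camera adjusted p = 0.0124, adjusted p = 0.408 with an estimated correlation, 0.00484 to 0.408 over all camera settings). Sdhc, a succinate dehydrogenase subunit, fell from 62.3 ± 20.6 to 24.9 ± 3.95 CPM (edgeR adjusted p = 0.00494). Genes of dioxygenases that use 2-oxoglutarate were higher, and many of these enzymes remove methyl groups from histones. Over this list 7 of 28 rose (12 adjusted over the list alone) and Alkbh3 fell (camera adjusted p = 0.00308, adjusted p = 0.388 with an estimated correlation, 0.000889 to 0.388 over all camera settings). The demethylase genes Kdm2b and Kdm4c rose from 53.1 ± 19.0 to 155 and from 12.6 ± 4.83 to 37.1 ± 6.20 CPM (edgeR adjusted p = 0.00111 and 0.00157). In the untreated control replicate 2 these lists already differed from replicates 1 and 3, by medians of -0.62, -0.38 and 0.40. With D-2HG the medians against all 3 controls, replicate 2 included, were -0.68, -0.41 and 0.53. The mean log2 CPM of the respiratory list was 7.35 to 7.52 in the D-2HG libraries, below the 7.69 of control replicate 2. The satellite share was also highest among the controls in that replicate.

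Glycolysis genes moved both ways. Slc2a3, Hk2 and Pfkfb3 rose and Tpi1, Pgk1 and Ldha fell among 19 measured (3 and 4 adjusted over the list alone; camera adjusted p = 0.589). Ldha, encoding lactate dehydrogenase A, fell from 4641 ± 1127 to 2524 ± 305 CPM (edgeR adjusted p = 0.0146). Tpi1, encoding triosephosphate isomerase, fell from 363 ± 108 to 150.1 ± 22.2 CPM (edgeR adjusted p = 0.00312). Hk2, encoding hexokinase 2, rose from 71.9 ± 5.90 to 112 ± 6.86 CPM (edgeR adjusted p = 0.0370). Among 11 genes tied to the making and removal of 2-hydroxyglutarate, Phgdh, Mdh1, Mdh2 and Ldha fell (1 up and 4 down adjusted over the list alone; camera adjusted p = 0.124). D2hgdh, which oxidises D-2HG, differed by -0.89 (-1.99 to 0.20, 95% interval) and Idh1 by -0.17 (-1.48 to 1.13), neither past the threshold (mean control CPM of 5.14 and 3.43). Hk2 lost its call without control replicate 1, control replicate 3, any D-2HG replicate or L-2HG replicate 1 in turn. Ldha lost its call without control replicates 1 or 3 or D-2HG replicates 1 or 3 (adjusted p up to 0.158 over the named genes that lost a call).

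Genes of several stress responses were higher with D-2HG. Of 16 NRF2 and pentose phosphate genes 5 rose, Hmox1, Txnrd1, Gclc, Abcc1 and Gsr (6 up and 1 down adjusted over the list alone; camera adjusted p = 0.0494, adjusted p = 0.408 with an estimated correlation, 0.000315 to 0.408 over all camera settings). Hmox1, encoding the heme-degrading enzyme heme oxygenase 1 (identifier ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), rose from 5.04 ± 2.68 to 32.3 ± 4.27 CPM, a log2 fold change of 2.62 ± 0.33 (SE; edgeR adjusted p = 6.32e-05). Txnrd1, encoding thioredoxin reductase, rose from 154 ± 49.5 to 398 ± 19.6 CPM (edgeR adjusted p = 0.000794). Of 10 osmotic stress genes, Hspa4l, Slc38a2 and Slc6a6 rose (3 adjusted over the list alone; camera adjusted p = 0.0252, adjusted p = 0.388 with an estimated correlation, 0.00956 to 0.388 over all camera settings). The chaperone gene Hspa4l rose from 31.9 ± 6.23 to 131 ± 6.44 CPM (edgeR adjusted p = 5.95e-06). The amino acid transporter gene Slc38a2 rose from 73.1 ± 4.23 to 241 ± 20.1 CPM (edgeR adjusted p = 0.000100). Of 13 p53 targets, Cdkn1a, Ccng1, Trp53inp1, Zmat3 and Polk rose (6 adjusted over the list alone; camera adjusted p = 0.0373, adjusted p = 0.319 with an estimated correlation, 0.00491 to 0.319 over all camera settings). Without control replicate 2, camera gave adjusted p = 0.238 for the NRF2 list and 0.0727 for both the osmotic and p53 lists. The NRF2 list also lost its call without D-2HG replicates 1 or 2 (adjusted p = 0.0715 and 0.0804) or L-2HG replicates 1, 2 or 3 (up to 0.0645). The p53 list lost it without D-2HG replicate 2 (0.107), control replicate 1 (0.0565) or L-2HG replicates 1, 2 or 3 (up to 0.0553), and the osmotic list lost it without L-2HG replicate 2 (0.0539). Control replicate 2 differed from replicates 1 and 3 by medians of -0.34, 0.22 and -0.04 over the 3 lists, against 0.48, 0.49 and 0.63 with D-2HG.

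Other fixed lists did not pass camera with D-2HG and held members that moved both ways or few that moved. Of 31 early activation genes 3 rose, including Ier3 (log2 fold change 1.40), and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.589). The log2 difference was -0.11 for Myc (95% interval -0.57 to 0.34), -0.26 for Cd69 (-0.69 to 0.18) and -0.03 for Il2ra (-0.41 to 0.34), none past the threshold. Of 22 naive and memory genes Il7r, Satb1, Il6st and Ccr9 rose and Id3 and Dapl1 were among those that fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.589). Ccr9, a chemokine receptor gene, rose to 58.7 ± 3.61 CPM against 20.2 ± 3.37 (edgeR adjusted p = 0.000240). Of 18 unfolded protein response genes 6 fell, including Herpud1 from 131 ± 0.451 to 74.7 ± 2.18 CPM, and Hyou1 and Sel1l rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.0567). HIF targets had 5 of 17 up and Fam162a down (5 and 3 adjusted over the list alone; camera adjusted p = 0.455). Camera adjusted p was 0.254 for ATF4 and amino acid genes (2 up, 4 down of 27; 3 and 5 adjusted over the list alone). It was 0.254 for sterol and fatty acid synthesis, where members that rose of 30 included Srebf2 and Acly (3 adjusted over the list alone). It was 0.254 for ribosome biogenesis (4 up and 3 down of 30; 4 and 4 adjusted over the list alone). It was 0.589 for one-carbon and nucleotide synthesis, where Atic rose and Shmt2, Adsl and Prps1 fell of 24 (1 and 3 adjusted over the list alone). For the cell cycle list, where Ccnd2, Mcm5 and Pcna fell of 19, it was 0.326 (2 adjusted over the list alone). For the heat shock list, where Hsph1 rose of 13, it was 0.624 (1 adjusted over the list alone). Of these lists, the unfolded protein response passed in 3 of 20 other camera settings (adjusted p down to 0.0102) and sterol synthesis in 1 (0.0392). By fry, a test of each list apart from other genes, the unfolded protein response, sterol synthesis, HIF target and 2-hydroxyglutarate handling lists passed too (adjusted p = 0.00603, 0.00699, 0.0139 and 0.0273), and the TCA cycle list did not (0.0744).

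Over all genes, 2278 of 10235 tested passed the threshold with D-2HG, 1205 higher and 1073 lower than in control (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05; 52.9% higher). The 6 named genes with the largest positive fold changes were Hmox1, Ercc6l, Gk, Rhoq, Gtf2ird1 and Lrp12. Gk, encoding glycerol kinase, rose from 11.0 ± 4.14 to 55.7 ± 11.3 CPM (edgeR adjusted p = 4.14e-05). Those with the largest negative ones were Ly6a, Gbp2, Cxcl10, Iigp1, Zbp1 and Igtp. Of the 48 named genes past the threshold, 34 passed with each of the 9 libraries left out in turn, including Gbp2, Ly6a, Igtp, Ifng, Ccl3, Pdcd1, Hmox1, Txnrd1, Hspa4l, Cox5b, Sdhc and Kdm2b. The 13 that lost their call without control replicate 3 included Ccng1, Gclc, Pfkfb3 and Slc6a6 (adjusted p up to 0.158), and the 12 lost without control replicate 1 included Ndufs8, Rhoq and Gtf2ird1 (up to 0.107). Calls were also lost without D-2HG replicates 1, 2 or 3 (up to 0.106, 0.0812 and 0.126) or L-2HG replicate 1 (up to 0.0589), each time with Hk2 among them. The share called higher was 70.0% with library totals alone, 41.0% with DESeq2's Wald test and 39.6% by edgeR without the count filter. The median log2 fold change of the 10235 genes was 0.10 with library totals against 0.04 with TMM. DESeq2 and the fit without the filter covered 43755 genes, with medians of 0.16 and 0.11. The count of genes was 450 without control replicate 1, 4257 without control replicate 2, 384 without control replicate 3, and 826 without D-2HG replicate 1, 1058 without D-2HG replicate 2, 641 without D-2HG replicate 3. It was 96 with the satellite share as a covariate, 78 in the 5 libraries of like satellite share, 1169 without the 2 treated libraries of highest satellite share and 5615 with limma-voom.

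The same comparison was made for L-2HG at the same dose and time. Interferon-inducible genes were lower with L-2HG too, with 8 of 25 list members down (10 down and 2 up adjusted over the list alone). Their mean log2 CPM was 4.17 ± 0.01 against 4.66 ± 0.04 in control (SD, n = 3; camera adjusted p = 0.00724, adjusted p = 0.176 with an estimated correlation, 0.000230 to 0.176 over all camera settings). Gbp2 fell from 282 ± 37.7 to 82.7 ± 17.4 CPM, a log2 fold change of -1.78 ± 0.21 (SE; edgeR adjusted p = 0.000159), and Ly6a from 106 ± 27.9 to 16.7 ± 6.33 CPM (edgeR adjusted p = 0.000159). Il7r, the gene of the interleukin 7 receptor that naive and memory T cells carry (identifier ENSMUSG00000003882, chromosome 15, 9505788 to 9530176), rose from 64.7 ± 14.9 to 214 ± 13.8 CPM (1.73 ± 0.21 on the log2 scale; edgeR adjusted p = 0.000159). Pdcd1 fell from 516 ± 136 to 208 ± 40.1 CPM (edgeR adjusted p = 0.00386). Cd200 fell from 49.7 ± 5.77 to 16.2 ± 8.69 CPM (edgeR adjusted p = 0.00799). Spry2, an inhibitor of receptor tyrosine kinase signalling, and Ak7, an adenylate kinase gene, fell, with log2 fold changes of -2.80 and -2.56 (edgeR adjusted p = 0.00159 and 0.00193). Mcm5, part of the helicase that replicates DNA, fell from 169 ± 5.96 to 79.2 ± 12.5 CPM (edgeR adjusted p = 0.00557). Hmox1 differed by -0.08 (-0.98 to 0.81, 95% interval) and did not pass the threshold.

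Cytokine genes Ifng, Xcl1, Ccl3 and Ccl4 fell of 16 measured (6 adjusted over the list alone; camera adjusted p = 0.00724, adjusted p = 0.373 with an estimated correlation, 0.00299 to 0.399 over all camera settings). Pdcd1, Cd160, Cd200 and Pdcd1lg2 fell of 10 inhibitory receptor genes (4 adjusted over the list alone; camera adjusted p = 0.0175, adjusted p = 0.373 with an estimated correlation, 0.0105 to 0.373 over all camera settings). The inhibitory list lost its call without L-2HG replicate 1 (camera adjusted p = 0.0562). Ifng fell from 8.21 ± 3.15 to 1.37 ± 1.19 CPM (edgeR adjusted p = 0.0276). Xcl1, encoding the chemokine lymphotactin, fell from 5864 ± 1607 to 2956 ± 1139 CPM (edgeR adjusted p = 0.0237). Respiratory chain genes were lower, with 13 of 33 down (30 adjusted over the list alone; camera adjusted p = 1.80e-08, adjusted p = 0.373 with an estimated correlation, 1.97e-10 to 0.373 over all camera settings). Ndufs8 fell to 99.7 ± 23.3 CPM from 222 ± 60.2 (edgeR adjusted p = 0.00852). Of 22 TCA cycle genes 6 fell and Ogdh rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00724, adjusted p = 0.373 with an estimated correlation, 0.00284 to 0.373 over all camera settings). Of 28 dioxygenase genes 9 rose, including Kdm2b and Tet3 (11 up and 3 down adjusted over the list alone; camera adjusted p = 0.0178, adjusted p = 0.393 with an estimated correlation, 0.00242 to 0.674 over all camera settings). That list lost its call without control replicates 1 or 3 (camera adjusted p = 0.0524 and 0.0562) or L-2HG replicates 1 or 2 (0.0760 and 0.107). Control replicate 2 differed from replicates 1 and 3 by medians of -0.62, -0.38, 0.40 and -0.34 over the respiratory, TCA cycle, dioxygenase and cytokine lists. With L-2HG the medians against all 3 controls, replicate 2 included, were -0.64, -0.38, 0.54 and -0.57. The mean log2 CPM of the respiratory list ran from 7.09 to 7.69 in the L-2HG libraries, where control replicate 2 stood at 7.69.

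Chaperone and protein folding genes were lower with L-2HG. Hsp90aa1, Hspe1, Hspd1 and Stip1 fell of 13 heat shock genes (6 adjusted over the list alone; camera adjusted p = 0.00724, adjusted p = 0.373 with an estimated correlation, 0.00553 to 0.373 over all camera settings). Of 18 unfolded protein response genes 6 fell and Hyou1 and Edem1 rose (10 down and 2 up adjusted over the list alone; camera adjusted p = 0.00724, adjusted p = 0.176 with an estimated correlation, 0.00123 to 0.176 over all camera settings). Hspd1, a mitochondrial chaperonin, fell from 1388 ± 128 to 816 ± 49.2 CPM (edgeR adjusted p = 0.0155). Pdia3, a disulfide isomerase, fell from 1003 ± 216 to 501 ± 16.6 CPM (edgeR adjusted p = 0.00846), and Hspa5, the endoplasmic reticulum chaperone BiP, fell from 2507 ± 424 to 1434 ± 301 CPM (edgeR adjusted p = 0.0203). Ribosome biogenesis genes had 10 of 30 down, and Polr1b and Utp20 up (14 and 3 adjusted over the list alone; camera adjusted p = 0.00724, adjusted p = 0.373 with an estimated correlation, 0.00201 to 0.373 over all camera settings). The nucleolar protein gene Npm1 fell to 2948 ± 441 CPM from 5591 ± 1527 (edgeR adjusted p = 0.0156). Control replicate 2 differed from the other controls by medians of -0.44, 0.00 and -0.20 over the heat shock, unfolded protein and ribosome lists, against -0.47, -0.44 and -0.44 with L-2HG.

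Lists that did not pass camera with L-2HG included naive and memory genes, of which Il7r, Tcf7, Satb1, Ccr9, Il6st and Actn1 rose among 22 (7 adjusted over the list alone; camera adjusted p = 0.145). Osmotic stress genes Nfat5, Slc6a6, Slc38a2 and Hspa4l rose among 10 (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.131). Of 27 ATF4 and amino acid genes 7 fell and Slc7a1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0597). Of 24 one-carbon genes 5 fell and Atic rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0920). Among NRF2 genes Abcc1 rose and Tkt fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.218). Among p53 targets Trp53inp1 and Zmat3 rose (2 adjusted over the list alone; camera adjusted p = 0.475). Camera adjusted p was 0.292 for glycolysis (Slc2a3 and Pfkfb3 up, Slc2a1 and Aldoa down; 3 and 4 adjusted over the list alone). It was 0.218 for 2-hydroxyglutarate handling (Phgdh and Mdh2 down; 3 adjusted over the list alone). It was 0.972 for early activation (4 up and 3 down of 31; 5 and 5 adjusted over the list alone). It was 0.556 for HIF targets (Kdm3a, Pfkfb3 and Pfkfb4 up, Slc2a1 down; 4 and 3 adjusted over the list alone) and 0.218 for sterol synthesis (Fasn, Scd2 and Acly among those up; 4 adjusted over the list alone). Genes fixed in advance that did not pass had 95% intervals of -0.89 to 0.26 for Il2, -0.35 to 0.47 for Tnf, -1.94 to -0.09 for Gzmb, -0.79 to 0.13 for Myc, -0.76 to 0.11 for Cd69 and -0.67 to 0.09 for Il2ra. The intervals were -1.04 to -0.09 for Ldha, -0.08 to 0.83 for Hk2, -1.49 to 0.84 for D2hgdh and -1.51 to 1.39 for Idh1. For the cell cycle list, with Uhrf1 up and Cdc45, Mcm5 and Pcna down, it was 0.475 (1 and 3 adjusted over the list alone). Of these lists, ATF4 genes passed in 6 of 20 other camera settings, all of them among the 9 fits without 1 library (adjusted p down to 0.0227). Naive and memory genes passed in 4 (down to 0.0182), and one-carbon and osmotic stress genes in 1 each (0.0192 and 0.0388). By fry the naive and memory, one-carbon, sterol synthesis, osmotic stress and p53 lists passed too (adjusted p = 0.00546, 0.00885, 0.00885, 0.0346 and 0.0346).

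Over all genes, 1812 of 10235 passed the threshold with L-2HG, 963 higher and 849 lower than in control (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05; 53.1% higher). The 6 named genes with the largest positive fold changes, Abca13, Muc16, Dock4, Mdga2, Prlr and the olfactory receptor gene Olfr1489, had few counts. They stood highest in L-2HG replicate 3, the library with the largest share of sensory receptor counts (3251 CPM). Muc16 was at 42.9 ± 42.1 CPM with L-2HG against 4.38 ± 3.66 in control. Muc16, Dock4, Mdga2, Olfr1489 and Prlr lost their call without L-2HG replicate 3 (adjusted p up to 0.199). The 6 with the largest negative ones were Spry2, Ak7, Ly6a, Cxcl10, Fcrl1 and Epcam. Gbp2, Ly6a, Il7r, Pdcd1, Cd200, Spry2, Ak7 and Mcm5 were the 8 of 50 named genes that passed with each of the 9 libraries left out in turn. The others lost their call without control replicate 3 (42 genes, among them Ndufs8, Pdia3 and Gbp7), control replicate 1 (35), L-2HG replicate 1 (25) or L-2HG replicate 2 (12), with adjusted p up to 0.150, 0.178, 0.121 and 0.137. Hspe1 and Muc16 also lost it without any D-2HG replicate (up to 0.0844), Muc16 without control replicate 2 (0.0864). The share called higher was 77.7% with library totals alone, 31.7% with DESeq2's Wald test and 31.0% by edgeR without the count filter. The median log2 fold change of the 10235 genes was 0.15 with library totals against 0.05 with TMM. DESeq2 and the fit without the filter covered 43755 genes, with medians of 0.57 and 0.41. The count of genes was 177 without control replicate 1, 4108 without control replicate 2, 65 without control replicate 3, and 394 without L-2HG replicate 1, 744 without L-2HG replicate 2. It was 8 with the satellite share as a covariate, 12 in the 5 libraries of like satellite share, 679 after subtraction of a genomic DNA background and 427 in a fit of the L-2HG and control libraries alone.

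**Figure D3:**
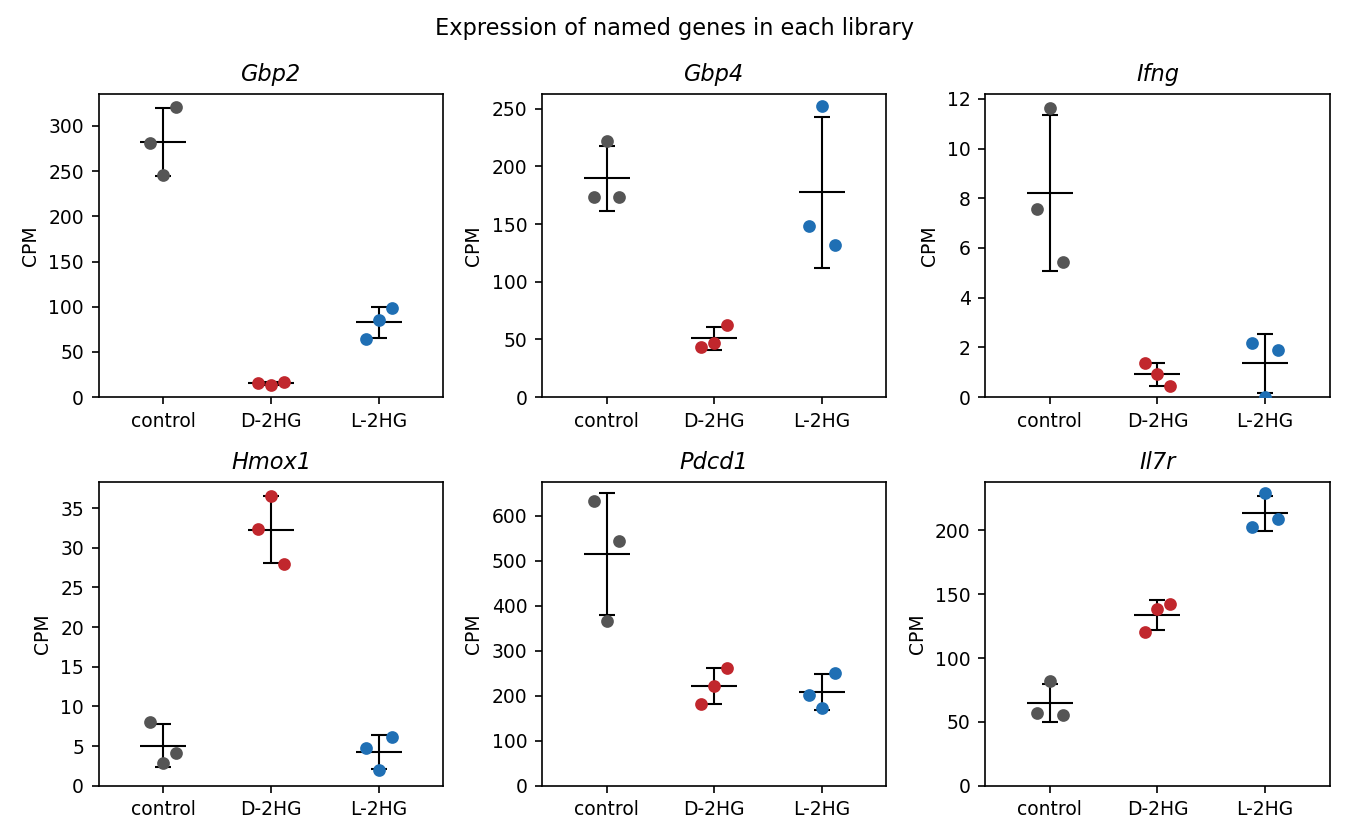
CPM of 6 genes in each library (points), with the group mean (long bar) and SD (short bars, n = 3), on linear axes that start at 0. Gbp2, Gbp4 and Hmox1 differed between D-2HG and L-2HG, Pdcd1 stood at 222 ± 40.2 and 208 ± 40.1 with the 2 compounds against 516 ± 136 in control, and Il7r was higher with each compound.

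The enantiomers were compared directly, at 20 mM and 6 h for both. Interferon-inducible genes separated them, with 10 of 25 list members lower with D-2HG than with L-2HG (11 adjusted over the list alone). The difference in mean log2 CPM was -1.04 (95% interval -1.19 to -0.90; camera adjusted p = 1.62e-19, adjusted p = 0.000947 with an estimated correlation, 4.50e-24 to 0.000947 over all camera settings). Gbp2 stood at 15.4 ± 1.86 CPM with D-2HG and 82.7 ± 17.4 with L-2HG (SD, n = 3), a log2 difference of -2.43 ± 0.24 (SE; edgeR adjusted p = 1.97e-05). Gbp4 was at 50.9 ± 9.97 against 178 ± 65.5 CPM (edgeR adjusted p = 0.00172), and with L-2HG it did not pass against control. Irgm2 and Tgtp2, GTPases of the immunity-related family, were lower, with log2 differences of -1.84 and -1.83 (edgeR adjusted p = 0.00204 and 0.00195), and so was Ly6a, at -1.96 (edgeR adjusted p = 0.0182). Hmox1 was higher with D-2HG, at 32.3 ± 4.27 against 4.30 ± 2.14 CPM (edgeR adjusted p = 0.00172).

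In all, 31 of 10235 genes passed the threshold between the compounds, 5 higher and 26 lower with D-2HG (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The genes higher with D-2HG were Hmox1, Zfand2a, Rgs1, Hspa4l and Esd. Rgs1, a regulator of G protein signalling, was at 61.3 ± 5.90 CPM with D-2HG and 22.6 ± 2.75 with L-2HG (edgeR adjusted p = 0.00612), both under the 90.6 ± 15.8 of control. The chaperone gene Hspa4l was at 131 ± 6.44 against 61.5 ± 8.31 CPM (edgeR adjusted p = 0.0182) and the esterase gene Esd at 647 ± 38.2 against a mean of 312 CPM (edgeR adjusted p = 0.0495). Of the 26 lower genes, 10 were on the interferon-stimulated list. NRF2 and pentose phosphate genes were higher with D-2HG as a list (camera adjusted p = 3.92e-08, adjusted p = 0.0880 with an estimated correlation, 3.22e-08 to 0.0880 over all camera settings). Of 16 members 5 were higher adjusted over the list alone, and Hmox1 passed over all genes. Their mean log2 CPM differed by 0.64 (0.37 to 0.90, 95% interval). Naive and memory genes were lower as a list (difference -0.34, -0.50 to -0.17; camera adjusted p = 0.000182, adjusted p = 0.0406 with an estimated correlation, 1.62e-05 to 0.0406 over all camera settings), with 4 of 22 lower adjusted over the list alone. The smallest adjusted p of a member over all genes was 0.0727, for Dapl1.

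Heat shock genes (0.42, 95% interval 0.16 to 0.68), ribosome biogenesis genes (0.21, 0.07 to 0.34), p53 targets (0.37, 0.14 to 0.60) and one-carbon genes (0.20, 0.06 to 0.34) had higher mean log2 CPM with D-2HG than with L-2HG. Camera gave adjusted p = 2.63e-05, 0.00257, 0.0194 and 0.0386 for them, and adjusted p = 0.2, 0.148, 0.137 and 0.148 with an estimated correlation. Over all camera settings the ranges were 3.61e-06 to 0.2, 0.000377 to 0.148, 0.00815 to 0.240 and 0.0173 to 0.160. The p53 list lost its call without any D-2HG replicate, L-2HG replicates 1 or 3 or control replicates 1 or 3 (camera adjusted p up to 0.232), and the one-carbon list without D-2HG replicate 2 or L-2HG replicates 1 or 2 (up to 0.150). In the main fit no difference was called for the respiratory chain list (0.01, -0.45 to 0.46), the TCA cycle list (0.06, -0.23 to 0.35), dioxygenases (0.09, -0.21 to 0.39), inhibitory receptors (-0.01, -0.49 to 0.46) or effector cytokines (-0.24, -0.53 to 0.04). Camera adjusted p for these were 0.986, 0.549, 0.437, 0.764 and 0.111. The intervals were -0.15 to 0.29 for glycolysis, -0.32 to 0.20 for 2-hydroxyglutarate handling, -0.19 to 0.07 for early activation, -0.11 to 0.24 for HIF targets and -0.11 to 0.31 for ATF4 genes. They were -0.15 to 0.14 for sterol synthesis, -0.20 to 0.15 for cell cycle, 0.00 to 0.51 for osmotic stress and -0.01 to 0.30 for the unfolded protein response, with camera adjusted p from 0.0966 to 0.899. Of these lists, effector cytokines passed in 6 of 20 other camera settings (lower with D-2HG, adjusted p down to 0.0102) and osmotic stress genes in 2 (down to 0.0421). By fry the unfolded protein response passed too (adjusted p = 0.0364). For single genes the 95% intervals were -2.52 to 0.70 for Ifng, -0.84 to 0.35 for Il2, -0.40 to 1.51 for Gzmb and -0.78 to 0.17 for Ldha, none past the threshold. They were -0.71 to 0.11 for Tnf, -0.24 to 0.67 for Myc, -0.37 to 0.50 for Cd69, -0.12 to 0.64 for Il2ra, -0.18 to 0.72 for Hk2, -1.81 to 0.67 for D2hgdh and -1.58 to 1.35 for Idh1, also not past it. Over the 10235 genes tested, 62.6% had a 95% interval of the difference between the compounds within 2-fold in both directions.

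Gbp2, Gbp4, Irgm2, Tgtp2 and Hmox1 passed between the compounds with each of the 9 libraries left out in turn, while Gbp3, Zfand2a, Esd, Hspa4l, Ly6a, Zbp1 and Rgs1 did not. Of these, Gbp3 lost its call without any library but control replicate 2, and Zfand2a without any 1 of the treated libraries. Esd lost it without any D-2HG replicate, L-2HG replicates 1 or 2 or control replicate 3. Hspa4l lost it without any D-2HG replicate or L-2HG replicates 1 or 3, Zbp1 without any D-2HG replicate or L-2HG replicate 1, and Ly6a without D-2HG replicates 1 or 3 or L-2HG replicates 1 or 3. Rgs1 lost it only without L-2HG replicate 1. The adjusted p rose to 0.241, 0.250 and 0.137 without D-2HG replicates 1, 2 and 3, to 0.357, 0.129 and 0.355 without L-2HG replicates 1, 2 and 3, and to 0.0574 and 0.0988 without control replicates 1 and 3. The number of genes past the threshold was 16 without D-2HG replicate 1, 16 without D-2HG replicate 2, 13 without D-2HG replicate 3, 10 without L-2HG replicate 1, 15 without L-2HG replicate 3, 60 without control replicate 2. It was 49 with DESeq2's Wald test (26.5% higher with D-2HG, against 16.1%, and a median log2 difference of -0.20 over 43755 genes, where edgeR without the count filter had -0.08) and 158 with limma-voom.

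The changes with the enantiomers were then set against each other. Gbp2, Ly6a, Ifng, Pdcd1 and Cd200 were lower and Ccr9, Kdm2b and Slc38a2 higher with both compounds than in control. With L-2HG, Ifng, Kdm2b and Slc38a2 lost their call without control replicate 1 and without control replicate 3. Of the genes past the threshold, 579 were higher with both compounds and 542 were lower with both, where independent lists of these sizes would share 113 and 89.0. This overlap depends on single controls. The L-2HG calls behind it numbered 177, 4108 and 65 without control replicates 1, 2 and 3. Gm1966, a predicted gene, was the 1 gene that passed in opposite directions, at 11.0 ± 3.00 CPM with D-2HG and 43.9 ± 9.78 with L-2HG against 24.6 ± 7.36 in control (edgeR adjusted p = 0.00228 between the compounds). Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.825 and Spearman's rho = 0.834, and 84.5% had the same sign. Both comparisons share the 3 control libraries. In turn, 40 simulations of unchanged groups against these controls gave a mean r of 0.435 and rho of 0.426. They gave 65.1% of the same sign and 0 shared calls. Each gene was drawn independently there, so the simulations hold no library factor shared across genes. The covariance was 0.419 against 0.0604 simulated, a difference of 0.359. With 3 controls no split leaves 2 libraries on each side, so part of the excess may come from the shared controls or from such a library factor. Of the 1121 genes past the threshold in the same direction with both, 82.7% had an interval of the difference between the compounds within 2-fold. Of 1156 genes past it with D-2HG but not L-2HG, 16 differed between the compounds, and of 690 past it with L-2HG but not D-2HG, 2 did.

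**Figure D4:**
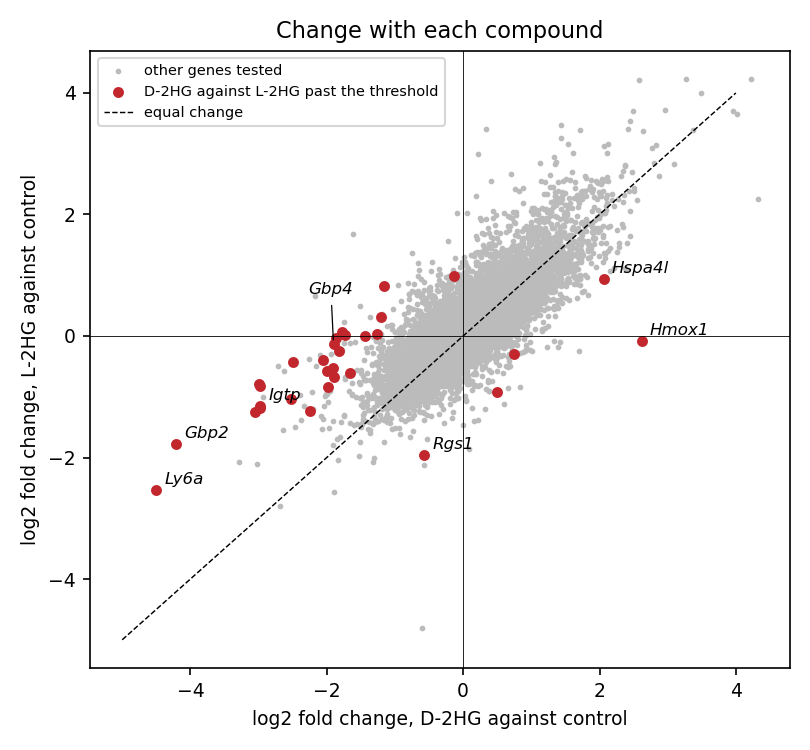
Log2 fold change against control of each tested gene with D-2HG (horizontal axis) and with L-2HG (vertical axis), with the 31 genes past the threshold between the compounds in red and the dashed line marking equal change. Gbp2 lies at -4.21 and -1.78, Hmox1 at 2.62 and -0.08.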

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

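Chosen after the results were seen were the tests of gene length and GC content, the 5 libraries of like satellite share, the control replicate 2 comparison for the respiratory chain, and the median change after background subtraction. The rule that a share is judged with its 95% interval was also added after the values were known. Gm1966 was the gene past the threshold in opposite directions, by -1.16 ± 0.29 with D-2HG and 0.82 ± 0.28 with L-2HG on the log2 scale, and the difference of -1.98 ± 0.30 (SE) passed by edgeR (adjusted p = 0.00228, Benjamini-Hochberg).

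With genes split in 3 by exon length, the longest had a median log2 fold change of 0.42 and the shortest -0.39 with D-2HG, and 0.45 and -0.35 with L-2HG, and fold changes rose with exon length (Spearman's rho = 0.471 with D-2HG and 0.461 with L-2HG, 0.0236 between the compounds). Control replicate 2, which has a satellite share of 5.35%, showed the same trend against control replicates 1 and 3 (rho = 0.438). It also had lower respiratory chain genes (median -0.62, where D-2HG had -0.68 against all 3 controls, replicate 2 included). A library factor unrelated to the compounds is therefore a candidate cause of both patterns, and after removal of the length and GC trend the respiratory median with D-2HG was -0.39, which leaves open whether part of it follows from the compounds. Within the treated groups the trend was weaker, with rho = 0.147 for D-2HG replicate 3 and 0.287 for L-2HG replicate 2, each against the other replicates of its group. Over the respiratory chain the same comparisons gave medians of -0.13 and -0.43, so that the D-2HG replicate with a satellite share of 17.0% against a mean of 5.31% showed little of the fall, which goes against this factor in that group. An effect of the compounds on long and short genes was not tested apart from this factor. The mean satellite share was higher with each compound than in control, though D-2HG replicate 2 (3.79%) lay below control replicate 2 (5.35%).

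Genomic DNA in the libraries may raise the counts of some genes, since the mean share of counts in silent sensory receptor genes was higher with each compound than in control. Not every library showed this. D-2HG replicate 2 held 745 CPM of the unscaled totals in these sensory receptor genes, below the 825 CPM of control replicate 2. After subtraction of a background estimated from those genes, 81.9% (79.6 to 84.0) of the genes higher with D-2HG and 48.0% (44.8 to 51.2) of those higher with L-2HG stayed called (exact 95% intervals). These intervals treat genes as independent draws, though the genes share the same libraries and background estimates. They do not measure the spread between libraries. The bounds set before this test, at least 80% against this source and under 50% for it, were met by the point values but not by the whole intervals, so that the test leaves it open for both compounds. The median log2 fold change of these genes was 1.04 after subtraction with D-2HG (from 1.01) and 1.08 with L-2HG (from 1.14), which argues against genomic DNA as the source of the whole change. Of the genes lower than control, 60.9% stayed called with D-2HG and 25.3% with L-2HG. Calls were thus lost more often among genes that added reads would not lower. A lost call therefore cannot be ascribed to genomic DNA, and the share of calls kept does not decide about it. The median log2 fold change of the lower genes still tested was -0.76 after subtraction with D-2HG (from -0.82) and -0.70 with L-2HG (from -0.82), so that most of their change stayed.

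The fall of interferon-inducible genes with D-2HG was weighed against several technical sources, and their difference between the compounds against a shallow library. The 16 members called lower in the full fit, and chosen by that fall, had a median log2 fold change of -2.51. After subtraction of genomic DNA it was -2.65. Genomic DNA adds reads, and the mean share of sensory receptor reads was higher with D-2HG than in control. Its subtraction therefore deepens such a fall and does not test this source. The median of the called members was -2.35 in the 5 libraries of like satellite share and -2.43 after removal of the length and GC trend. If these transcripts came from other cells, loss of such cells would lower their markers as much. The lowest median of the B cell, myeloid and dendritic lists was -0.90. These lists had 3, 1 and 3 tested members, too few to decide about other cells. The median difference between the compounds was -1.28 without the shallow L-2HG replicate 2, against -1.27 with it. These values argue against the satellite factor and the length and GC trend as the whole of the fall in the called members. They argue against the shallow library as the whole of the difference between the compounds. Loss of other cells stays open. An effect of D-2HG on interferon-inducible genes remains as a hypothesis.

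Each pair of groups has 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. The other splits mix both groups on each side. Any strong difference between the groups, whatever its cause, widens the spread there and lowers the counts. Those splits therefore do not show what unchanged groups would give. The real split gave 2278 genes and 9 lists, against at most 0 and 6 in the other splits for D-2HG and control. It gave 1812 genes and 9 lists, against at most 117 and 9 in the other splits for L-2HG and control. The 117 genes came from control replicates 1 and 3 with L-2HG replicate 3 against the rest. It gave 31 genes and 7 lists, against at most 0 and 6 in the other splits for D-2HG and L-2HG. The number of splits with as many, the real one included, was 1 for genes in each comparison, 2 for lists of L-2HG against control and 1 for lists in the other comparisons. Other splits that called no gene by edgeR were not run with another tool.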

How the results depend on the processing

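Chosen after seeing the data were the satellite covariate, the genomic DNA corrections, the fits without D-2HG replicate 3 and L-2HG replicate 2 or with 5 libraries, the deposited size factors and the length and GC offsets. Of single gene values under an alternative, 3303 kept direction and side of the threshold, 525 lost and 36 gained a call and 50 turned sign. Of list values 440 kept and 85 lost a call, counted only for lists called in the main fit, which could not gain one. Calls gained by other lists are given with each comparison above. Leaving out each library in turn gave 384 to 4257 genes with D-2HG, 65 to 4108 with L-2HG and 10 to 60 between the compounds, 6 to 10, 7 to 10 and 5 to 7 lists, and r from 0.746 to 0.864 between the compounds' fold changes. Depth limits the genes tested: thinned to the smallest library, the counts were 795 and 720 genes against control and 10 between the compounds, with fewer reads per gene.

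With D-2HG the count was 5615 genes by limma-voom, 1341 without the count filter, 907 with a minimum of 2-fold (fewer by construction), 96 with the satellite covariate, 1169 without D-2HG replicate 3 and L-2HG replicate 2, and 78 with 5 libraries (74 shared with the full fit; fewer samples). With L-2HG it was 5169 by limma-voom, 1195 with a mean count of at least 50, 427 with the 2 groups alone, 795 with a minimum of 2-fold and 679 after background subtraction. It was 1179 over genes with a low predicted background, 8 with the covariate, 560 without D-2HG replicate 3 and L-2HG replicate 2, 1089 with length and GC offsets and 12 with 5 libraries (9 shared). Between the compounds it was 49 by DESeq2, 158 by limma-voom, 76 with the covariate, 13 without D-2HG replicate 3 and L-2HG replicate 2, 52 with length and GC offsets and 63 with 5 libraries. With an estimated correlation camera called 1 list with D-2HG, 0 with L-2HG (9 with the preset value, 14 by fry) and 2 between the compounds. With L-2HG the covariate left 5 lists and 5 libraries 4. With the covariate, r across genes between the compounds was 0.729. The cause was not tested for these except where the construction is named.

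With the replicate number as a replicate block the counts were 2314 genes with D-2HG, 2284 with L-2HG and 35 between the compounds, 8, 9 and 7 lists, and r = 0.821. Samples share only a number: deviations of same-numbered samples correlated from -0.172 to 0.283, those of other pairs from -0.302 to 0.276.

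Log2 fold changes of D-2HG against control that turned sign were these. Il2 went from -0.56 to 0.34 (5 libraries). Tnf went from -0.24 to 0.28 (length and GC offsets). Gzmb went from -0.46 to 0.0045 (length and GC offsets). Myc went from -0.11 to 0.24 (the covariate), 0.20 (length and GC offsets), 0.23 (5 libraries). Cd69 went from -0.26 to 0.055 (5 libraries). Il2ra went from -0.032 to 0.020 (limma-voom), 0.045 (library totals), 0.036 (the mean count filter), 0.036 (background subtraction), 0.059 (low predicted background), 0.031 (the covariate), 0.026 (leaving out D-2HG replicate 3 and L-2HG replicate 2), 0.11 (5 libraries), -0.094 to 0.034 over fits without 1 library. Idh1 went from -0.17 to 0.27 (limma-voom), 0.088 (leaving out D-2HG replicate 3 and L-2HG replicate 2), 0.053 (length and GC offsets), -0.67 to 0.17 over fits without 1 library. None of these passed the threshold in the fit of all 9 libraries.

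Log2 fold changes of L-2HG against control that turned sign were these. Il2 went from -0.31 to 0.014 (thinning), 0.27 (the covariate), 0.58 (5 libraries). Tnf went from 0.062 to -0.064 (DESeq2), -0.22 (no filter), -0.11 to 0.19 over fits without 1 library. Myc went from -0.33 to 0.093 (the covariate), 0.17 (5 libraries). Cd69 went from -0.32 to 0.10 (5 libraries). D2hgdh went from -0.33 to 0.11 (limma-voom), -0.56 to 0.070 over fits without 1 library. Idh1 went from -0.061 to 0.041 (library totals), 0.0082 (leaving out D-2HG replicate 3 and L-2HG replicate 2), 0.15 (length and GC offsets), -1.35 to 0.49 over fits without 1 library. Hspe1 went from -0.67 to 0.010 (5 libraries). Of these, Hspe1 passed the threshold in the fit of all 9 libraries.

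Log2 fold changes of D-2HG against L-2HG that turned sign were these. Cd69 went from 0.065 to -0.033 (leaving out D-2HG replicate 3 and L-2HG replicate 2), -0.046 (5 libraries), -0.011 to 0.13 over fits without 1 library. Idh1 went from -0.11 to 0.67 (limma-voom), 0.024 (no filter), 0.080 (leaving out D-2HG replicate 3 and L-2HG replicate 2), 0.071 (5 libraries), -0.68 to 1.17 over fits without 1 library. None of these passed the threshold in the fit of all 9 libraries. The cause of these turns was not tested.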

Other observations

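Both tests given here were chosen after the results were seen, and the lists were drawn up after the fall of Gbp2 and its relatives was known. Genes outside the interferon-stimulated list also separated the compounds. Psmb9, an interferon-inducible subunit of the immunoproteasome, stood at 18.7 ± 4.96 against 46.9 ± 12.8 CPM with D-2HG and L-2HG (SD, n = 3; edgeR adjusted p = 0.0204, Benjamini-Hochberg). Samhd1, a dNTP hydrolase that restricts viruses, was at 38.8 ± 5.22 against 79.3 ± 6.52 CPM (0.0377), and Ifi47, an interferon-inducible GTPase, at 139 ± 11.4 against 286 ± 36.9 CPM (0.0182). The kinesin gene Kif21b was at 35.8 ± 2.33 against 79.8 ± 11.5 CPM (0.0182) and Plec, encoding the cytoskeletal linker plectin, at 13.6 ± 4.79 against 37.8 ± 8.85 CPM (0.0181). Cd55, a regulator of complement, was at 10.4 ± 0.937 against 25.0 ± 6.22 CPM (0.0394) and Lsp1, an actin-binding protein of leukocytes, at 40.2 ± 2.08 against 85.2 ± 29.5 CPM (0.0417).

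A candidate explanation for which interferon-inducible genes fell is lower interferon gamma signalling, as Ifng itself was lower. Ifng stood at 0.914 ± 0.462 CPM with D-2HG and 1.37 ± 1.19 with L-2HG, however, and did not pass between the compounds. At these low counts Ifng does not show a difference to match that of its target genes between the compounds. In a list of genes typical of interferon gamma 18 of 19 fell with D-2HG (median -2.06; camera adjusted p = 1.17e-22, adjusted p = 0.000598 with an estimated correlation) and 8 with L-2HG (median -0.57; 0.000124 and 0.0482). Of 9 tested genes typical of type I interferon, Irf7 and Rtp4 fell with D-2HG. Camera called this list lower (camera adjusted p = 0.0476, adjusted p = 0.119 with an estimated correlation), although its median was 0.15. Between the compounds the type I list was lower with D-2HG too (median -0.72; 0.000235 and 0.0130), as was the gamma list (median -1.77; 9.78e-38 and 0.000132). Control replicate 2 differed from control replicates 1 and 3 by a median of 0.54 over the type I list, more than the change with D-2HG, and by -0.004 over the gamma list. The medians with D-2HG differed by -2.21, but the lists were divided after the split was seen, so that this test leaves the explanation open. Among MHC class I presentation genes 7 of 19 fell with D-2HG, including Tap1, Psmb8, Psmb9 and H2-T23 (median -0.49; camera adjusted p = 0.000147, adjusted p = 0.119 with an estimated correlation). Control replicate 2 differed from control replicates 1 and 3 by a median of -0.40 over the MHC genes, and this comparison was added to the test after the values were seen, so that it too leaves the explanation open. Whether less interferon gamma lowered these genes cannot be told from transcript counts of a single time point.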
